A study of Mus musculus with 2 samples.

How the data were processed

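Per the labels, the tissue was layer of hippocampus from male mice aged 18 to 20 months. Their strain was B6CASTF1/J, the F1 hybrid of the B6 and CAST strains, per the labels. Open chromatin was mapped in this tissue by DNase-seq. In this assay, nuclei are treated with DNase I, which cuts where DNA is accessible, and the cut ends are sequenced. The labels name 1 group of 2 samples, biological replicates 1 and 2. Both replicates carry the same donor record and different tissue records in the labels, and nothing in them says that the tissue came from separate animals, so any spread between the replicates may be technical. No condition was compared with another.

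Each replicate had 2 peak lists, a list of footprints and a list of bases with their false discovery rate (FDR), all on mm10 and made from the alignments of that library alone, per the text supplied with the files. The peak caller, the footprint caller, their versions and their thresholds were not given in the sources used here. Column 7 of the deposited peak lists holds the authors' signal per peak. Within each list every signal was a whole multiple of 1 step (100% of values within 0.05 of a whole multiple), so that signal was taken to be tags per M sequenced tags (M, mega) around the peak. On that reading the steps imply 127 M tags in replicate 1 and 239 M in replicate 2, and the median peak rests on 83 and 110 tags, a counting error of 11.0% and 9.53%. The signal is the authors' own value and was used to describe, rank or filter peaks within a list. The deposited p-value column of the FDR lists gives an FDR per run of bases and reaches 0.0499. The value in the p-value column of the deposited footprint lists was 0.01 throughout and was taken as the threshold of the call.

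The longer peak list of each replicate was the main set. Each of its peaks held a base at an FDR of 0.05 or less, and each peak of the shorter list held a base at 0.001 or less. The rule set beforehand, to prefer the list with narrower intervals, gave opposite answers in the 2 replicates, and the longer list was narrower on average. The shorter list was used as an alternative.

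Peaks were placed on the GRCm38 (mm10) sequence and the GENCODE M21 annotation, which holds 21938 protein-coding genes, 21853 of them with a coding transcript. A promoter was the 1000 bp on each side of any transcription start site (TSS) of a protein-coding gene. Remaining peaks were assigned to exon, intron or intergenic sequence in that order. Peaks were called shared where they overlapped a peak of the other replicate by at least 1 bp, and shares were compared with 20 seeded placements of the other list within chromosomes. Shares carry Wilson 95% intervals, which cover counting error only. Correlations of log2 signal, and the ranking of shared peaks by signal, were taken across peaks paired 1 to 1. Counts of shared peaks at loci are counts of 59643 regions, made by merging the shared peaks of both replicates where they overlapped or touched. Peaks are not replicates and no p-value was computed across them.

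Gene groups were 27 lists: pan-neuronal, excitatory neuron, dentate granule cell, CA1 pyramidal cell, CA2 and CA3 pyramidal cell, inhibitory neuron, astrocyte, oligodendrocyte, oligodendrocyte precursor, microglia, endothelial and mural cell, choroid plexus and ependyma, thalamus and habenula, neocortex layers, striatum, cerebellum, blood and red cell, liver, striated muscle, skin epithelium, immediate early, aged and activated glia, glutamate and GABA receptor, neuropeptide, housekeeping, circadian clock and Hox genes. Of their symbols, 364 matched the annotation and 1 did not. Some genes stand in more than 1 list. For each list and replicate, members with a promoter peak were compared with all other protein-coding genes by a two-sided Fisher's exact test. For the peak load of a locus, peaks in the gene body and 10 kb on each side were divided by the mean of the 200 genes nearest in locus length. The median of a list was then placed among 10000 seeded random lists of the same size matched on decile of length, with a two-sided p. Both tests were adjusted over the 27 lists by Benjamini-Hochberg, and a list was called only where the adjusted p was under 0.05 in the same direction in both replicates. Genes are not replicates, so these tests describe each replicate's peaks.

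Footprints were compared between replicates against 20 seeded shuffles within the union of peaks. For 24 consensus strings, the share of matches in peaks whose midpoint lay in a footprint was divided by the share of peak bases in footprints. This ratio was set against 20 permutations of the consensus with the same number of CG. A string was called where it lay above or below all its permutations in both replicates, and at least 10 permutations had to have a match.

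The genes named in the text were fixed by rule: in each list the 2 members with the highest and the 1 with the lowest mean peak load, the 15 loci with the highest load of shared peaks among those expected to hold at least 2, the 5 longest loci without a shared peak, the 5 shared peaks with the highest mean rank of signal, and all consensus strings. Lists, tests, the naming rule and most alternatives were fixed before the data were examined. The alternatives were the shorter peak list, peaks at or above the median signal, chromosomes 1 to 19, equal numbers of peaks, other definitions of overlap (50% of both intervals, or the centre of the peak), FDRs of 0.01 and 0.001, promoter windows of 500 and 2500 bp, the 5′ end of each gene, loci with 0 or 50 kb added, promoter peaks left out, footprints widened by 5 bp or limited to peaks, and each replicate left out in turn.

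Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, pysam 0.24.0 and matplotlib 3.10.9, together with bedtools 2.31.1, samtools 1.23.1 and BLAST+ 2.17.0. The steps for locus load, promoter lists, shared peaks and footprints at motifs were tested on simulated data. In 200 simulated lists of 12 genes, the test of peak load was scored on replicate 1 alone, by an unadjusted p under 0.05. It passed in 7.0% of lists with no change, in 64.0% with loads raised 2-fold and in 96.5% with loads raised 4-fold. The promoter test, scored in the same way, passed for 2.0% of 200 lists of 14 random genes and for 100% of lists with all members open. A call needed an adjusted p under 0.05 in both replicates, which is stricter, so these are not the rates of the calls.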

Results

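Open chromatin of tissue labelled layer of hippocampus was profiled by DNase-seq in male B6CASTF1/J mice aged 18 to 20 months. The 2 samples were biological replicates of 1 group, so the data addressed which genes and regions were open in this tissue, which sequence motifs were protected within them, and how far the replicates shared them. Replicate 1 had 86064 peaks over 21.4 Mb (0.808% of the genome), and replicate 2 had 198583 peaks over 41.8 Mb (1.58%), a mean of 142324 ± 79563 (SD, n = 2). Median peak width was 215 bp and 200 bp. The steps in the signal imply 127 M and 239 M tags, so the library with more tags had the longer list.

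Promoters of the pan-neuronal, glutamate and GABA receptor and immediate early lists were open in both replicates, whereas those of Hox, blood and liver genes mostly lacked a peak. All 25 genes for glutamate and GABA receptors, which carry fast and modulatory synaptic transmission, had a promoter peak in each replicate, as did all 12 pan-neuronal genes, all 17 immediate early genes, which are induced by neuronal activity, all 16 housekeeping genes and all 15 circadian clock genes. Over all protein-coding genes, 13759 of 21853 (63.0%) had a promoter peak in replicate 1 and 14744 (67.5%) in replicate 2, with 13545 in both. Of the Hox genes, which pattern the body axis caudal to the forebrain, 1 of 20 had a promoter peak in replicate 1 and 3 in replicate 2. Blood genes had 3 and 2 of 14, and liver genes 1 and 2 of 12.

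By Fisher's exact test, the receptor genes were more often open than other genes (adjusted p = 0.000153 in replicate 1 and 0.00103 in replicate 2). The same held for immediate early (0.00376 and 0.0122), housekeeping (0.00449 and 0.0122), circadian clock (0.00706 and 0.0161) and pan-neuronal genes (0.0159 and 0.0326). Hox (adjusted p = 2.2e-06 and 5.19e-05, Fisher's exact test), blood (0.0116 and 0.000841) and liver genes (0.00128 and 0.00293) were less often open. With a promoter window of 2500 bp the pan-neuronal, housekeeping, circadian clock and liver calls ended. The 5′ end of each gene ended the immediate early and pan-neuronal calls, and the shorter peak list ended the pan-neuronal call.

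Cell type markers gave mixed values. Excitatory neuron promoters were open in 11 of 12 genes in replicate 1 (adjusted p = 0.0828, Fisher's exact test) and in 12 in replicate 2 (0.0326), so the list passed in replicate 2 alone. Astrocyte genes also passed in replicate 2 alone, with 7 and 12 of 12 open. Neocortex layer genes passed in replicate 1 alone, with 10 and 9 of 10. Microglia (4 and 9 of 14), choroid plexus and ependyma (1 and 4 of 10) and striated muscle genes (3 and 8 of 12) were less often open in replicate 1 alone. Passing in 1 replicate was not counted as a call.

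The remaining lists passed in neither replicate. Dentate granule cell genes were open in 9 of 12 in replicate 1 and 11 in replicate 2, CA1 pyramidal cell genes in 8 and 10 of 10, and CA2 and CA3 genes in 10 and 11 of 12. Inhibitory neuron genes were open in 6 and 12 of 14, oligodendrocyte genes in 5 and 13 of 14, and oligodendrocyte precursor genes in 6 and 9 of 10. Endothelial and mural cell genes were open in 6 and 7 of 14, and aged and activated glia genes in 9 and 12 of 19. Among genes of other brain regions, thalamus and habenula had 8 and 8 of 10, striatum 9 and 10 of 10, and cerebellum 7 and 6 of 12. Neuropeptide genes had 9 and 9 of 16, and skin epithelium genes 3 and 6 of 10. All 10 CA1 and all 10 striatum genes were open in replicate 2 and still did not pass. For these short lists that replicate left no room for a call of more often open, so the missing call does not speak against one.

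Peak load was also compared over whole loci. The loci of immediate early, excitatory neuron, circadian clock and housekeeping genes held more peaks than genes of similar length in both replicates, and no list was called with fewer when matched on length alone. The median immediate early locus held 3.06 times the length-matched mean in replicate 1 and 2.38 times in replicate 2, against medians of 0.743 and 0.852 in random lists, and 15 and 16 of its 17 members lay above 1. Excitatory neuron loci reached 2.37 and 3.13 times, circadian clock loci 2.17 and 1.499 times, and housekeeping loci 1.62 and 1.75 times.

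Among immediate early genes, the load was 5.54 ± 0.68 (SD, n = 2) at Egr3, a zinc finger factor on chromosome 14 (70077203 to 70082614), and 5.10 ± 0.17 at Junb, a subunit of AP-1 on chromosome 8 (84974484 to 84978718). It was 0.795 ± 0.221 at Homer1, a postsynaptic scaffold, whose promoter signal was 4.11 ± 2.21. In the excitatory list, Nrgn, a calmodulin-binding postsynaptic protein encoded on chromosome 9 (37544492 to 37552904), had 10 and 25 peaks, 5.85 ± 2.22 times the expected number. Tbr1, a transcription factor of glutamatergic neurons, had 5.02 ± 3.12 times and Grin2b, an NMDA receptor subunit, 0.877 ± 0.054 times. Of the clock genes, Nr1d1, the repressor REV-ERB alpha on chromosome 11 (98767932 to 98775333), had 24 and 20 peaks (7.19 ± 2.71 times), Dbp, a clock output factor, 6.05 ± 0.08 times, and Nr1d2, a paralogue of Nr1d1, 0.626 ± 0.167 times. Gapdh, a glycolytic enzyme, had 5.08 ± 1.98 times, Tubb5, a beta-tubulin, 3.61 ± 0.52 times, and Psmb2, a proteasome subunit, 0.410 ± 0.156 times.

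Adjusted p over the random lists was 0.0027 and 0.00135 for immediate early, 0.0036 and 0.00135 for excitatory neuron, 0.0027 and 0.0387 for circadian clock and 0.0351 and 0.00135 for housekeeping loci. Pan-neuronal (1.13 and 1.78 times) and neuropeptide loci (1.33 and 1.57 times) passed in replicate 2 alone. The excitatory call ended with 50 kb added or with the shorter list, and the housekeeping call with 0 or 50 kb added or without promoter peaks. With random lists also matched on GC content, chosen after the data were seen, the circadian call ended, as the random median in replicate 2 moved from 0.885 to 1.09. In that setting receptor genes were called with more peaks (adjusted p = 0.0441 and 0.00324, by permutation of lists) and Hox genes with fewer (0.0018 and 0.0027).

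**Figure D1:**
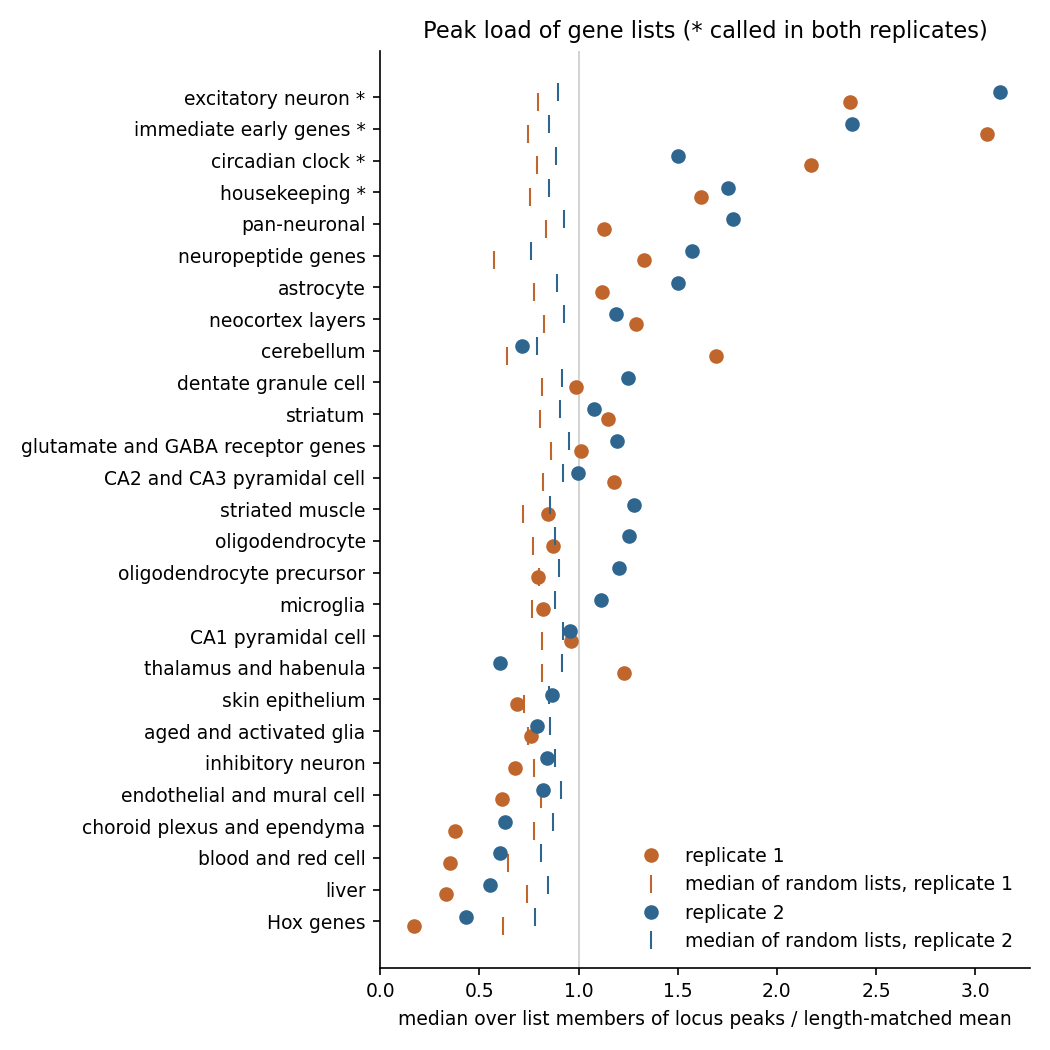
Peak load of the 27 gene lists: the median over members of locus peaks divided by the length-matched mean (horizontal axis, no unit) for replicate 1 and replicate 2 (points) and the median of random lists of the same size (ticks). Immediate early and excitatory neuron genes lie above 2 in both replicates, and Hox genes lie lowest at 0.169 and 0.435.

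In the lists that were not called, members differed widely in load. The load was 3.97 ± 0.79 (SD, n = 2) at Sox9 and 2.12 ± 0.59 at Slc1a3, an astrocyte factor and a glutamate transporter, 2.49 ± 0.08 at Olig1 and 2.55 ± 0.38 at Pdgfra, genes of the oligodendrocyte lineage, and 2.79 ± 1.05 at Sall1, a factor of microglia. Fezf2, a factor of deep-layer neurons, had 5.36 ± 0.40 times, Zic2, a zinc finger factor, 5.84 ± 0.81 times, and Ppp1r1b, a regulator of protein phosphatase in striatal neurons, 2.76 ± 0.48 times. Celf4 and Eno2, pan-neuronal genes for an RNA-binding protein and an enolase, had 2.93 ± 1.39 and 2.88 ± 1.24 times. Grik5, a kainate receptor subunit, had 4.26 ± 1.72 times, Adcyap1, which encodes the neuropeptide PACAP, 3.07 ± 0.32 times, and Epor, the erythropoietin receptor, 3.28 ± 0.72 times. The lowest members of the same lists included Fgfr3 (0.502 ± 0.319; astrocyte), Ermn (0.408 ± 0.578; oligodendrocyte), Gpr17 (0.468 ± 0.661; oligodendrocyte precursor), Tmem119 (0.148 ± 0.209; microglia), Foxp2 (0.436 ± 0.099; neocortex layers), Zic1 (0.136 ± 0.192; cerebellum), Isl1 (0 and 0.241 in the replicates; striatum), Stmn2 (0.918 ± 0.347; pan-neuronal), Gria4 (0.425 ± 0.110; receptors) and Vip (0.498 ± 0.106; neuropeptides).

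Other members differed between the replicates. Olig2, an oligodendrocyte lineage factor, had 0 peaks in replicate 1 and 22 in replicate 2, and Dlx2, a factor of inhibitory neurons, 0 and 16. Hoxd13 had 18 and 3 peaks, Barhl2 16 and 1, Shox2 15 and 3, and Sox17 7 and 0, all developmental transcription factors. At the low end, Cldn5, a tight junction gene of endothelium, S100a9, a gene of neutrophils, Serpina1a, a gene of liver, Cst7, a cystatin, and Hoxc13 had no peak in either replicate.

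Hippocampal subfield lists were not called. In the dentate granule list, Plk5, a kinase-like gene, had 2.36 ± 0.10 times (SD, n = 2), Glis3 1.82 ± 0.54 times and Dsp, a desmosomal gene, 0.484 ± 0.014 times. Fibcd1, Zbtb20 and Dcn, CA1 genes, had 1.70 ± 1.12, 1.54 ± 0.21 and 0.367 ± 0.123 times. Tyro3, Bok and Map3k15, of the CA2 and CA3 list, had 2.42 ± 1.11, 2.42 ± 0.32 and 0.293 ± 0.160 times.

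Shared peaks at loci were counted as regions, with overlapping shared peaks of both replicates merged. Across all genes, Nfic, a nuclear factor I gene on chromosome 10 (81396186 to 81455635), held 28 shared peaks, 8.83 times the number expected for its length. Gabbr1, the GABA-B receptor subunit on chromosome 17 (37045966 to 37075067), held 22 (8.71 times), and Thra, the thyroid hormone receptor alpha on chromosome 11 (98740638 to 98769006), 20 (8.10 times). Fam171a2 (7.50), Prdm8 (6.41), Kdm6b (6.20), Celf5 (6.17), Sfi1 (5.95), Chst1 (5.59), Bahcc1 (5.51), Clcn2 (5.44), Irs2 (5.35) and Ppfia3 (5.31 times) followed. Sfi1 had no promoter peak in either replicate, and a shared peak in its window (chromosome 11, 3124641 to 3124940) had 11560 other matches in the genome, so its count is a poor measure of the gene. Windows of Thra and Nr1d1 overlap, as do those of Nfic and Celf5, so they share peaks. Gm20388 (16.7 times) and Fgfr2 (6.36 times) have annotated models whose loci span 4455 kb and 2981 kb, and their counts are no measure of the genes named.

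The longest loci without a shared peak were Malrd1, Skint5, Skint6, Trdn and Gm45194, with 8.73 to 13.965 shared peaks expected. Skint genes encode proteins of skin and thymus, and Trdn encodes triadin of muscle. Malrd1, on chromosome 2 (15526479 to 16255555), had 0 peaks in replicate 1 and 8 in replicate 2.

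Among shared peaks paired 1 to 1, the 5 of highest signal lay outside promoters. The highest, on chromosome 17 (39846781 to 39846920), lay in an annotated ribosomal RNA gene, with a signal of 63.6 in replicate 1 and 55.1 in replicate 2. The next lay in an exon of Lars2, a mitochondrial leucyl-tRNA synthetase, on chromosome 9 (123461881 to 123462140; 29.2 and 36.0). The others lay in intergenic sequence on chromosomes 3 (5860361 to 5860530, nearest gene Gm8797) and 6 (49236421 to 49236640, 7393 bp from Tra2a) and in an intron of Il31ra, a cytokine receptor, on chromosome 13 (112578141 to 112578340). Each of these 5 sequences had another match of at least 90% identity in the genome. Places 4 to 7 were tied at a mean rank of 6.0, and of these a peak in an exon of Cers5 on chromosome 15 (99735641 to 99736080; 23.4 and 21.05) had no such match.

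Peaks lay far more often at promoters than placed peaks did, and more so in replicate 1. Promoters held 31.5% (Wilson 95% interval 31.2 to 31.8) of replicate 1 peaks, 10.7 times the share of shuffled peaks, and 15.9% (15.8 to 16.1) of replicate 2 peaks, 5.65 times, a mean of 23.7 ± 10.98% (SD, n = 2). Introns held 30.01% and 40.3%, intergenic sequence 28.5% and 35.3%, and exons 10.01% and 8.46%. Among shared peaks the promoter share was 33.5% and 33.9%, and among private peaks 24.6% and 6.79%. With equal numbers of the highest-signal peaks, chosen after the data were seen, replicate 2 had 24.2% at promoters.

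**Figure D2:**
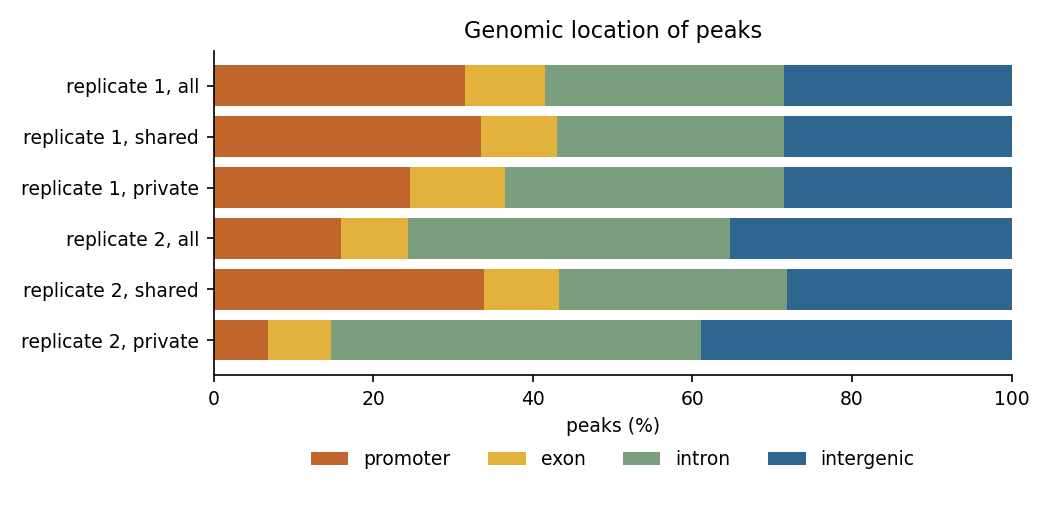
Share of peaks (%, horizontal axis) at promoters, exons, introns and intergenic sequence, for all, shared and private peaks of each replicate. Promoters hold 33.5% and 33.9% of shared peaks and 6.79% of the peaks private to replicate 2.

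The X chromosome, present in 1 copy in males, had fewer peaks per Mb and a lower median promoter signal than every autosome. It held 13.1 peaks per Mb in replicate 1 and 34.7 in replicate 2, 0.401 ± 0.047 (SD, n = 2) of the autosome median, against lowest autosomal values of 27.4 and 70.1 on chromosome 3. Median signal of X promoter peaks was 0.593 and 0.477, 0.543 ± 0.016 of the autosome median, and below all 19 autosomes in both replicates. With peaks at or above the median signal alone, density fell to 0.216 of the autosome median, and in replicate 2 the X promoter signal lay above 3 autosomes.

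**Figure D3:**
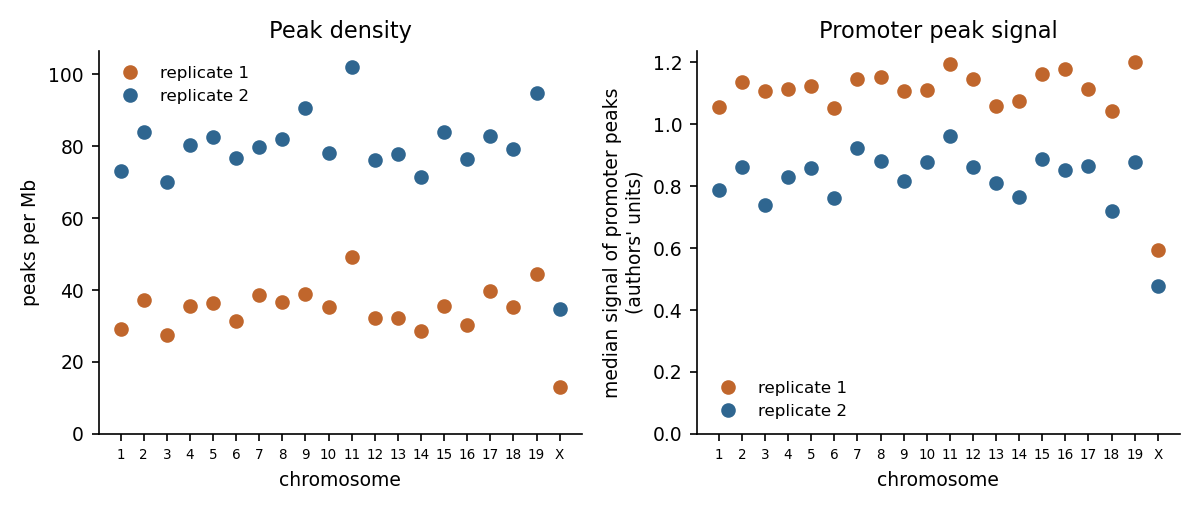
Peaks per Mb (left) and median signal of promoter peaks in the authors' units (right) for each autosome and X, with a point per replicate. X lies lowest in both panels, at 13.1 and 34.7 peaks per Mb and promoter signals of 0.593 and 0.477.

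Footprints are short stretches protected from DNase I within open chromatin. They covered consensus matches for CTCF, NRF1, CREB, EGR, NFI, CEBP and NEUROD-type factors more often than matches to any of their permuted strings. Of the matches to the CTCF consensus, the insulator protein, 78.3% of 3477 in replicate 1 and 90.4% of 6769 in replicate 2 lay in a footprint, 8.03 ± 2.11 times (SD, n = 2) the share of peak bases in footprints. NRF1, a regulator of mitochondrial and housekeeping genes, had 7.41 ± 2.07 times, and CREB (TGACGTCA), the cyclic AMP response factor, 5.77 ± 1.42 times. EGR (GCGTGGGCG), bound by factors of the immediate early response, had 5.22 ± 0.11 times. NFI had 4.30 ± 1.54 times on 53 and 161 matches, and CEBP 3.07 ± 0.05 times on 96 and 156. NEUROD-type bHLH sites, bound by factors of excitatory neurons, had 2.80 ± 0.62 times on 5145 and 20250 matches.

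These 7 strings lay above all their permutations in both replicates, and none of the 24 lay below. The highest permuted string reached 2.47 and 3.33 for CTCF and 1.07 and 1.86 for NEUROD. ASCL bHLH (1.91 ± 0.02; SD, n = 2), RFX (3.75 ± 0.90) and YY1 (5.21 ± 0.62) lay above them in 1 replicate. Within the permuted range lay ZBTB33 (4.91 ± 0.30), ETS (2.78 ± 0.07), NF-Y (1.29 ± 0.15), HNF4 (1.07 ± 0.07), AP-1 (0.891 ± 0.262), PU.1 (0.872 ± 0.019), ROR (0.620 ± 0.071), MEF2 (0.590), SOX (0.569 ± 0.108), GATA (0.542 ± 0.194), homeobox (0.405 ± 0.069) and HNF1 (0.241 ± 0.341). REST (2.67 ± 0.37) and SP/KLF (4.24 ± 0.53) had too few permuted strings with a match for a call. In peaks without a TSS within 1000 bp the CEBP call ended. With footprints widened by 5 bp the 7 calls held at lower ratios, from 4.71 ± 1.03 for CTCF and 4.37 ± 0.96 for NRF1 to 2.04 ± 0.46 for NEUROD. The sequence preference of DNase I was not modelled here.

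**Figure D4:**
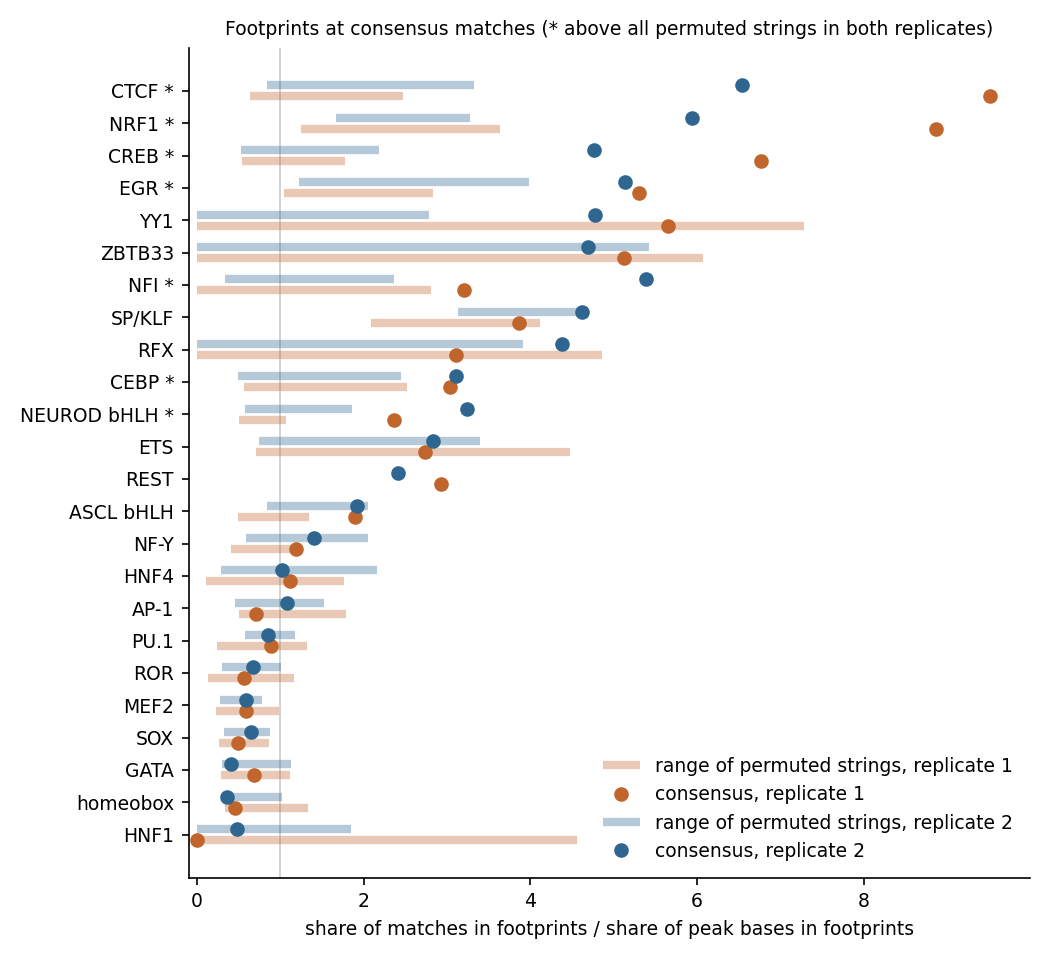
Share of consensus matches in footprints divided by the share of peak bases in footprints (horizontal axis, no unit) for 24 motifs, with a point per replicate and a bar for the range of permuted strings. CTCF lies furthest out, at 9.52 and 6.54, and 7 strings lie above their bars in both replicates.

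Replicate 1 had 195780 footprints and replicate 2 516559, a mean of 356170 ± 226825 (SD, n = 2), with median widths of 8 and 10 bp. In their own peaks lay 85.6% and 88.3% of them, and 70.1% and 81.0% of peaks held a footprint. In the lowest decile of signal 22.4% and 35.3% of peaks held a footprint, and in the highest 99.3% and 99.98%. At least 1 bp was shared with a footprint of the other replicate for 45.5% (Wilson 95% interval 45.3 to 45.7) of replicate 1 footprints and 15.7% (15.6 to 15.8) of replicate 2 footprints, 2.47 and 2.09 times the shuffled share. With 50% overlap of both footprints, 23.01% and 8.72% were shared.

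Peaks of replicate 1 were largely found again in the longer list of replicate 2. Of replicate 1 peaks, 77.0% (Wilson 95% interval 76.7 to 77.3) overlapped a replicate 2 peak, 20.5 times the shuffled share of 3.76%. Of replicate 2 peaks, 33.8% (33.6 to 33.97) overlapped a replicate 1 peak, 20.3 times the shuffled 1.66%. The share rose with signal, from 36.3% to 97.2% between the lowest and highest decile in replicate 1 and from 6.52% to 91.9% in replicate 2. Requiring 50% of both peaks gave 39.3% and 17.0%, and equal numbers of the highest-signal peaks gave 58.9% and 58.2%.

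Across 52544 peaks paired 1 to 1, log2 signal correlated with a Pearson coefficient of 0.807 and a Spearman coefficient of 0.781, and peaks are not independent replicates. The median of the paired log2 differences, replicate 2 minus replicate 1, was 0.53 (1.45-fold), whereas over all peaks of each list the median signal was 0.656 in replicate 1 and 0.460 in replicate 2. Private peaks were weaker: 19798 in replicate 1 had a median signal of 0.419 against 0.759 in shared peaks, and 131536 in replicate 2 had 0.364 against 0.983. Private peaks had median widths of 118 and 192 bp, against 240 and 224 bp for shared peaks. At an FDR of 0.05, 30.9 Mb in replicate 1 and 67.2 Mb in replicate 2 were significant, with 25.9 Mb in both (83.9% and 38.5%).

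**Figure D5:**
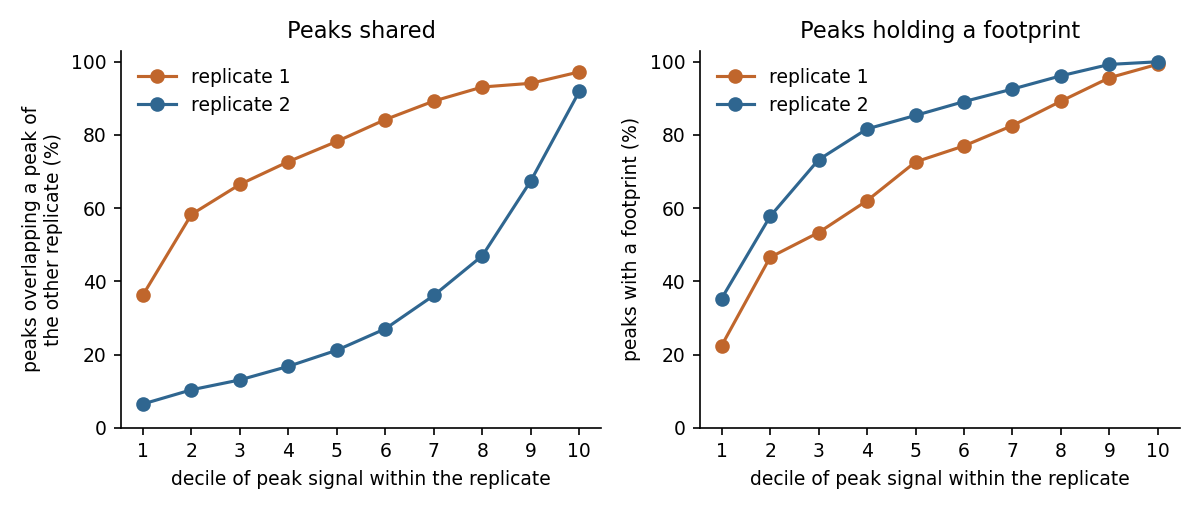
Share of peaks overlapping a peak of the other replicate (left, %) and share of peaks holding a footprint (right, %) by decile of peak signal within each replicate. Both rise with signal, to 97.2% and 91.9% shared and to 99.3% and 99.98% with a footprint in the highest decile.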

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

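Alternatives chosen only after the result was seen were random lists matched on length and GC content, equal numbers of peaks for the promoter share, and footprints shuffled within the same region. Among lists called in the main setting, 0 results reversed under the alternatives, and reversal was not scored for other lists or values. Of 189 promoter results for lists, 171 kept their side of the threshold, 7 lost and 11 gained it. Of 216 locus results 206 kept it, 6 lost and 4 gained it, and of 48 motif results 46 kept it, CEBP lost it without promoter peaks and MEF2 gained it with wider footprints. Only lists called in the main setting could lose it: 5 more often and 3 less often open, and 4 with more peaks per locus. Leaving a replicate out could not end a call, as a call needed both replicates. Of 480 values for named genes, 321 moved by less than the spread between replicates and 159 by at least that much. Random lists matched on GC content leave these loads unchanged by construction, and that setting is counted among the 321. Loads given for named genes are those of the main setting. Of 72 summary values 40 moved by less than their spread or by under 1.5-fold.

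Where a cause is not given, the cause was not tested. The shorter list, by its construction with fewer peaks, gave a mean of 82833 peaks and shared shares of 79.3% and 28.1%. Peaks at or above the median signal, again fewer, numbered 71684.5 on average, with shared shares of 91.5% and 53.7%, a promoter share of 35.4%, 6 lists with promoters less often open, an X density of 0.216 and an X promoter signal of 0.803 of the autosome median. Overlap of 50% of both intervals gave shared shares of 39.3% and 17.0%, a Pearson coefficient of 0.783, 52218 private peaks in replicate 1 and shared footprint shares of 23.01% and 8.72%. With the peak centre the shares were 60.5% and 26.3%, and with equal numbers of peaks 58.9% and 58.2%. Footprints inside peaks were shared at 41.4% and 13.7%, and shuffling within the same region left 1.86-fold and 1.65-fold excesses. At an FDR of 0.001, 13.2 Mb were shared. A promoter window of 2500 bp left 2 lists more often open and the 5′ end of each gene 3. With 50 kb added, 2 lists had more peaks per locus, and matching on GC content gave 1 list, Hox genes, with fewer. Without a replicate the values ranged from 86064 to 198583 peaks, 195780 to 516559 footprints, 6 to 7 lists more often and 3 to 6 less often open, and 4 to 6 lists with more peaks per locus.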

Other observations

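Of the tests reported here, that of list length, the control of the GC test, the sharing of replicate 1 peaks at loci, counts of Y-linked genes and the densities of motifs were chosen only after the result was seen. Gene families named by prefix beforehand differed widely in promoter peaks. Of 1134 olfactory receptor genes, 23 had a promoter peak in replicate 1 and 89 in replicate 2, 20 of them in both. Vomeronasal receptors had 3 and 8 of 331, and keratin-associated proteins 2 and 8 of 57. Zinc finger genes of the Zfp series were open in 344 and 351 of 397, ribosomal protein genes in 88 and 89 of 98, histone genes in 63 and 64 of 95, and solute carriers in 250 and 272 of 385. Clustered protocadherins, adhesion genes that mark single neurons, had 17 of 57 in replicate 1 and 46 in replicate 2. The Y chromosome held 32 and 132 peaks, and promoter peaks were found in both replicates at Kdm5d (signal 0.577 and 1.04), Eif2s3y (0.988 and 1.502), Uty (0.466 and 1.81) and Ddx3y (0.735 and 1.87), broadly expressed Y-linked genes, picked after their values were seen.

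Motif density in peaks, apart from footprints, was above all permuted strings in both replicates for 10 motifs. The CTCF consensus was 41.3 and 58.1 times as frequent as the mean of its permutations, RFX 11.4 and 18.1 times, NEUROD-type bHLH 2.84 and 6.04 times, NRF1 5.19 and 7.02 times, CREB 4.87 and 4.47 times and ETS 3.81 and 3.21 times. YY1 had 27.6 and 19.03 times and ZBTB33 25.9 and 26.0 times. SP/KLF (4.61 and 4.43 times) and REST (193 and 280 times, on 29 and 42 matches) were the others, and rest on 7 and 2 permuted strings with a match, so the REST ratio is taken over a mean of 0.15 matches and gives no size. AP-1, bound by Fos and Jun proteins, had 1.18 and 1.94 times and lay within its permuted range. In peaks without a TSS within 1000 bp, 8 motifs lay above: ETS (1.45 and 1.28 times), YY1 (4.58 and 2.5 times) and ZBTB33 (1.67 and 2.18 times) no longer did so in both replicates, and EGR (2.16 and 2.84 times) did.

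Promoters took a larger share of peaks in replicate 1 than in replicate 2, by 15.5 percentage points over the full lists. With equal numbers of the highest-signal peaks 7.25 points were left, which argues against list length as the whole cause. Equal numbers do not equalise depth, so other effects of depth on which peaks were found remain open. Standardising both lists of equal number to the same distribution of GC content left 18.8% of the 7.25 points (28.8% against 27.4% at promoters). A change in promoter peaks alone, whatever their GC content, would leave 66.7% or 56.5%, depending on which list is changed. Within the 20 bins of GC content the difference took both signs, such as 9.74% against 2.56% at promoters in bin 1 and 61.5% against 63.6% in bin 17, so the small remainder is in part a balance. A different preference of the libraries for GC-rich sequence is a candidate explanation. Peaks outside promoters in the lists of equal number also differed. Their median GC content was 52.0% in replicate 1 and 49.2% in replicate 2. The standardisation cannot tell such a preference from another cause that changed the GC content of the peaks found. Its control covers only a change in promoter peaks. Some peaks overlapped an earlier peak of their own list, 4518 of 86064 in replicate 1 and 3296 of 198583 in replicate 2. Promoter shares were not recomputed on merged regions. No biological explanation was tested, as the design gives no group to set against it.

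Loci of oligodendrocyte genes held few replicate 2 peaks that replicate 1 also had, 31.4% of 156 against 44.2% expected from signal, GC content and promoter position, a difference of -12.8 percentage points where random lists had a median of -3.18. This lay at percentile 2.34 of random gene lists (adjusted p = 0.21 over the 27 lists, by permutation of lists), within simulation error of the 2.5 bound. Hox (percentile 0.16) and striated muscle genes (0.84) lay lower and pan-neuronal genes as low (2.17), whereas astrocyte (11.4) and excitatory neuron genes (5.28) did not. Of replicate 1 peaks at oligodendrocyte loci, 94.0% of 50 were shared against 84.4% expected (percentile 98.35, adjusted p = 0.128, by permutation of lists), whereas Hox (0.13) and striated muscle genes (0.71) were low there too and pan-neuronal genes lay at 14.5. Oligodendrocyte precursor (99.67), neuropeptide (99.26) and inhibitory neuron genes (99.25) lay higher still for replicate 1 peaks. For replicate 2 peaks the precursor genes lay at 32.45. No list passed after adjustment for the peaks of either replicate and lists were not tested against each other, so fewer oligodendrocyte nuclei in the tissue of replicate 1 and a general difference between the libraries cannot be told apart.

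The highest signals may come from reads shared between near-identical copies of a sequence. Of the 20 shared peaks with the highest signal, 10 (50%) had another match of at least 90% identity over at least 50% of their length, against 9.0% of 200 shared peaks drawn at random. The 3 highest, which include the ribosomal RNA gene and the Lars2 exon, were among them, the Cers5 exon, in the tie that followed, was not, and 0 of the 20 matched the mitochondrial genome. The other 10 had no such match, so copies of that length and identity in the genome sequence leave their signal unexplained. Shorter or more diverged copies, and copies absent from that sequence, would be missed by the search. No biological explanation was tested.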
